A study of Homo sapiens with 12 samples.

How the data were processed

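The deposited count tables hold raw read counts per gene symbol, whole numbers with no normalization by the authors, for RNA-seq and Ribo-seq of 3 genotypes. Per the submitters' processing notes, the sources name Bowtie2, TopHat2, edgeR and the human build hg19, with no version. The counting tool, the annotation and the strand setting are not given in the sources used here, so counts of overlapping or antisense genes are uncertain. The authors also deposited 6 comparison tables of each knockout against WT for RNA-seq, Ribo-seq and translation efficiency (TE). Per the file headers, their fold changes are on a log2 scale and their significance values are unadjusted and adjusted p-values. The tool behind the authors' TE tables is not given in the sources used here, and 28 and 27 genes there have no p-value.

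Counts were analysed with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes with low counts were removed with filterByExpr, which left 15637 of 27011 genes in RNA-seq and 14722 in Ribo-seq, and libraries were scaled by TMM within each assay. A quasi-likelihood F-test in edgeR (two-sided, Benjamini-Hochberg adjusted p under 0.05) was fitted over the 6 libraries of an assay, so that the 3 genotypes shared 1 estimate of the spread. The common biological coefficient of variation was 0.0862 in RNA-seq and 0.119 in Ribo-seq. TE was tested as the Ribo-seq change minus the RNA-seq change over 12 libraries and 13257 genes. The comparisons, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. A total of 9 comparisons were fitted, each knockout against WT and the knockouts against each other in RNA-seq, Ribo-seq and TE. The overlap of the knockouts was set beside 50 simulations in which groups differed from shared controls by chance alone.

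Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 31 lists of a comparison, and again with an estimated correlation and with fry. The lists were the 4EHP-GIGYF complex and binding partners; deadenylation, decapping and 5′ decay factors; the microRNA pathway; ribosome collision and quality control; cap binding and translation initiation; immediate early genes; ERK feedback genes; AU-rich element mRNAs; and interferon-stimulated genes. Others were integrated stress response and ATF4 targets, the unfolded protein response, heat shock chaperones, cholesterol synthesis, p53 targets, G1/S and DNA replication genes, G2/M and mitosis genes, and nuclear-encoded oxidative phosphorylation genes. Cell-type and signalling lists were collagens and extracellular matrix, neuronal, epithelial, fibroblast and mesenchymal, and leukocyte genes, Wnt targets, TGF-beta and BMP targets, and glycolysis and hypoxia genes. The remaining lists were cytosolic ribosomal proteins, other 5′ TOP mRNAs, zinc finger genes, mitochondrial ribosomal proteins, protocadherins and replication-dependent histones. A list of mitochondrially encoded mRNAs could not be tested, since the count tables hold none of them.

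Genes were named by a rule. It took EIF4E2, GIGYF1 and GIGYF2 in every readout, and for each knockout against WT in RNA-seq, Ribo-seq and TE the 6 genes up and 6 down with the largest change among called genes. These needed an average log2 CPM of at least 2 and, in RNA-seq and Ribo-seq, both knockout libraries on the same side of both WT libraries, and non-coding or uncharacterised symbols were passed over. It also took up to 2 members up and 2 down per list, with the smallest adjusted p, 4 per direction between the knockouts, and 6 per direction among genes that changed alike in both knockouts. The rule named 219 genes, of which the text prints mainly those whose call held in every fit that left out a library.

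A group with 0 counts was set at a floor of 3 counts per library, and folds with 1 to 3 counts are given with 95% counting intervals. Intervals and floors cover counting error only. Of the tested genes, 130 in 57 sets have counts identical to another gene in all libraries, and protocadherins, SNAR-A genes, HSPA1A and HSPA1B, and histone copies share reads, so their levels are uncertain.

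The alternatives were RLE and upper-quartile scaling, no filter and a stricter filter on low counts, DESeq2, limma-voom, the newer quasi-likelihood option of edgeR, a minimum fold of 1.2 with glmTreat, only the libraries of the genotypes compared, the replicate number as a block, and leaving out each library in turn. After the data were examined, fits without the genes in runs of neighbours, with identical genes counted once, and with protein-coding genes alone were added. Runs were found as running medians over 25 neighbouring genes in 11594 genes against 200 shuffled orders. Gene order came from a RefSeq table of another assembly than hg19, used only for neighbours, which matched 25468 genes (94.3%). Runs of at least 20 genes are drawn and were tested further, and shorter runs, down to 1 gene, count where genes or calls are said to lie in runs. Some genes that the rule for named genes chose, and 1 gene family, are not reported here.

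The procedure was tested on simulated data with 200 genes changed by 1.5-fold, 2-fold or 4-fold. In RNA-seq it recovered 82.1% and 71.6% of 1.5-fold (4EHP-null and GIGYF1/2-null designs), 98.5% of 2-fold in both, and all 4-fold changes. In the same order Ribo-seq gave 17.9% and 23.9%, 80.6% and 79.1%, and all. TE gave 14.9% and 11.9%, 71.6% and 73.1%, and 98.5% and 100%. These rates cover the changed genes only and may be lower at low counts. Between 3.91% and 9.56% of calls were false. Camera called a list moved by 0.4 (log2) and 0 others, with correlated genes untested. The search for runs found 34 of 40 neighbours moved by -0.5 and 1 other gene.

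The fold changes were compared with the authors' tables. Across shared genes, Pearson's r of the log2 fold changes was 0.999986 and 0.99999 in RNA-seq, 0.999961 and 0.999964 in Ribo-seq, and 0.979 and 0.994 in TE, for 4EHP-null and GIGYF1/2-null cells. The authors' tables call 2246 and 1988 genes in RNA-seq, 648 and 629 in Ribo-seq, and 50 and 15 in TE. Among genes in those tables, 1657 of 1659 and 1485 of 1493 of the RNA-seq calls made here, 315 of 315 and 265 of 265 of the Ribo-seq calls, and 4 of 4 TE calls in each knockout were also called by the authors. The deposited gene widths were used only for matching lists, and nothing else in the deposited tables was left out.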

Results

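Messenger RNA abundance (RNA-seq) and ribosome-protected mRNA fragments (Ribo-seq, a measure of translation) were sequenced from HEK293T cells, a human embryonic kidney line. By their labels, the cells were wild type (WT), null for 4EHP (4EHP-null), or null for both GIGYF1 and GIGYF2 (GIGYF1/2-null). Each genotype had 2 libraries per assay, 12 in all, from cells grown for 24 h in 15 cm dishes. RNA-seq libraries held 26143118 to 38175701 counts and Ribo-seq libraries 6536493 to 10816080, over 27011 genes. The series record calls the libraries biological replicates, and the labels do not say whether these were separate cultures or separate clones, so p-values measure the spread between these samples. Levels are in CPM (counts scaled to a common library size) as mean ± SD over 2 libraries. Changes are log2 fold changes ± standard error with 2 libraries per genotype, and adjusted p-values are from edgeR for genes and from camera for gene lists.

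EIF4E2 encodes 4EHP, a cap-binding relative of eIF4E, and its mRNA fell in 4EHP-null cells from 123 ± 0.0741 to 48.8 ± 3.02 CPM (-1.33 ± 0.08, adjusted p = 5.92e-07). Its ribosome-protected fragments fell from 35.8 ± 3.26 to 14.5 ± 3.34 CPM (-1.31 ± 0.18, adjusted p = 0.00284), a call that ended without 4EHP-null Ribo-seq replicate 2. In GIGYF1/2-null cells EIF4E2 mRNA was at 134 ± 4.28 CPM and was not called (adjusted p = 0.353). GIGYF1, a scaffold protein that binds 4EHP, fell in GIGYF1/2-null mRNA from 41.0 ± 0.292 to 24.2 ± 2.55 CPM (-0.76 ± 0.11, adjusted p = 6.91e-04). It lies in a run of neighbouring genes that fell together. Its ribosome-protected fragments fell from 7.71 ± 1.40 to 2.22 ± 0.738 CPM (-1.73 ± 0.29, adjusted p = 0.0120), a call that ended without WT Ribo-seq replicate 1. GIGYF2, the paralogue of GIGYF1, was not called in GIGYF1/2-null cells in mRNA (0.28 ± 0.11, adjusted p = 0.124) or in ribosome-protected fragments (-0.21 ± 0.22, adjusted p = 0.671). These counts do not show the loss of GIGYF2 that the label states, and its protein was not measured here. In 4EHP-null cells the mRNAs of GIGYF1 (adjusted p = 0.732) and GIGYF2 (adjusted p = 0.584) were not called. Between the knockouts, EIF4E2 mRNA was higher in GIGYF1/2-null cells (1.46 ± 0.08, adjusted p = 1.99e-07) and GIGYF1 mRNA lower (-0.69 ± 0.11, adjusted p = 6.23e-04). GIGYF2 mRNA was higher there (0.38 ± 0.11, adjusted p = 0.0222), a call that ended without 4EHP-null replicate 1 or 2 or GIGYF1/2-null replicate 1.

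**Figure D1:**
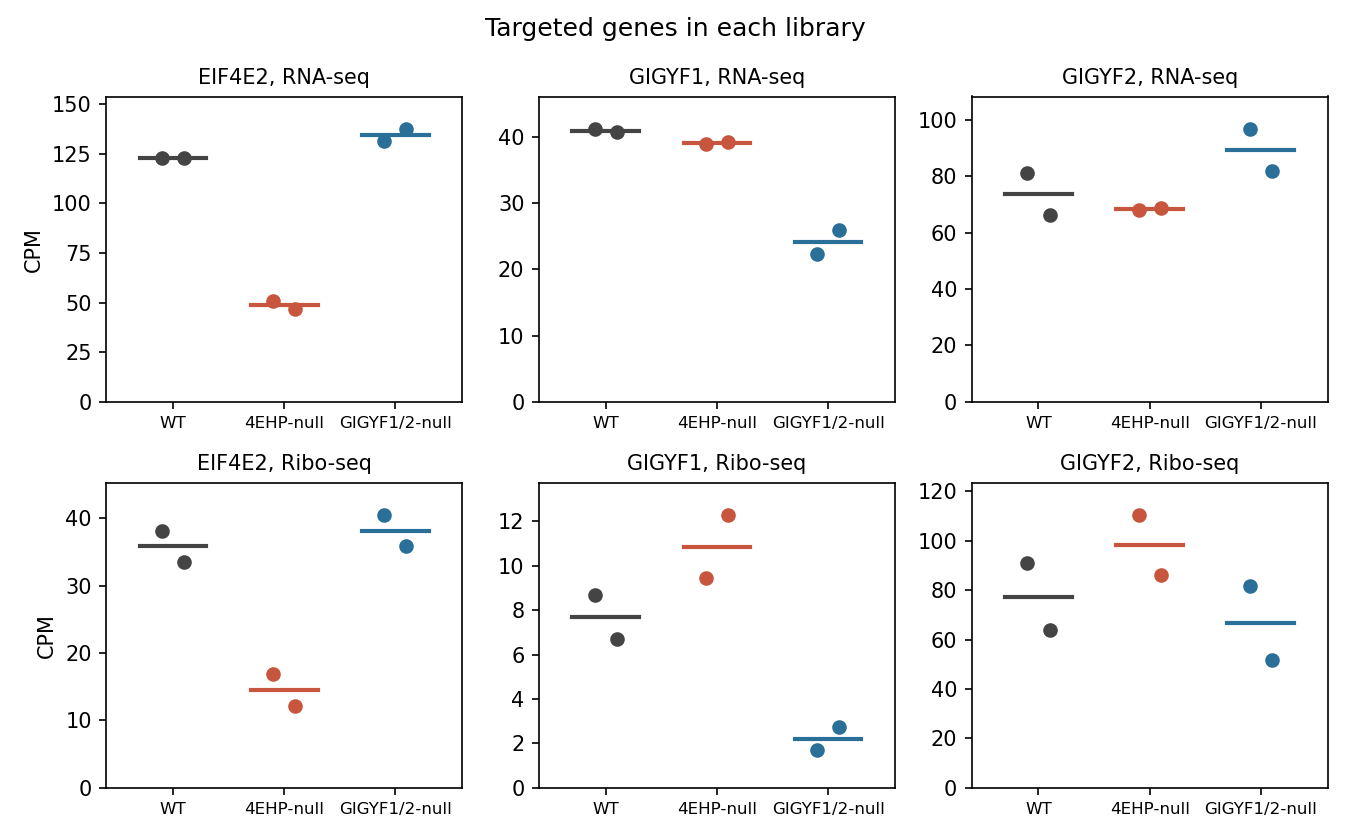
RNA-seq and Ribo-seq levels of EIF4E2, GIGYF1 and GIGYF2 in CPM (vertical axis) for each genotype (horizontal axis), with a point per library and a line at the mean of 2. EIF4E2 mRNA sits at 123 CPM in WT and 48.8 CPM in 4EHP-null cells, GIGYF1 mRNA at 41.0 CPM in WT and 24.2 CPM in GIGYF1/2-null cells, and GIGYF2 mRNA at 73.7 and 89.3 CPM in WT and GIGYF1/2-null cells.

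The comparison of 4EHP-null with WT RNA-seq asks which mRNAs change in abundance when 4EHP is lost. BST2, a membrane protein that holds budding viruses at the cell surface, rose from 4.34 ± 0.665 to 80.7 ± 4.66 CPM (4.22 ± 0.13, adjusted p = 4.20e-09). GPC3, a glypican of the cell surface, rose from 43.9 ± 0.942 to 202 ± 1.79 CPM (2.20 ± 0.08, adjusted p = 7.32e-09), and GFRA3, a receptor for the growth factor artemin, rose by 4.36 ± 0.24. TENM1, a teneurin of neuronal membranes, fell from 28.7 ± 2.26 to 0.801 ± 0.268 CPM (-5.19 ± 0.21, adjusted p = 1.48e-08). Also lower were the transcription factor SALL3 (-6.29 ± 0.36), the synaptic adhesion gene NRXN3 (-5.15 ± 0.26), the secreted Wnt antagonist SFRP1 (-4.11 ± 0.18) and NELL2 (-3.92 ± 0.17). FAM21C (1.85 ± 0.09) and ARHGAP22 (1.76 ± 0.11) rose within a run of neighbouring genes. PLCG2 rose by 2.63 ± 0.66 with levels of 51.1 ± 58.2 CPM, a call that ended in DESeq2, in limma-voom and without WT replicate 1, WT replicate 2 or 4EHP-null replicate 2. Of 15637 genes tested with edgeR, 1012 rose and 1036 fell, 2048 in all, of which 202 and 241 changed at least 2-fold. Without genes in runs of neighbours of either knockout 769 rose and 648 fell. The total was 810 without WT replicate 1, 818 without WT replicate 2, 1125 without 4EHP-null replicate 1 and 919 without 4EHP-null replicate 2.

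Ribosome and mitochondrial genes made up 3 of the 6 lists that fell in 4EHP-null mRNA. Cytosolic ribosomal protein mRNAs fell: of 78 measured, 0 rose, 47 fell and 31 were not called (1 and 69 adjusted over the list alone). The median was -0.36 (adjusted p = 2.54e-23, and adjusted p = 0.603 with an estimated correlation). RPL36A (-0.83 ± 0.10) and RPL4 (-0.61 ± 0.09, in a run of neighbours) were examples. The 47 that fell became 14 without WT replicate 1, 5 without WT replicate 2, 10 without 4EHP-null replicate 1 and 17 without 4EHP-null replicate 2. For the other 5′ TOP mRNAs, whose leaders start with a pyrimidine tract, of 16 measured, 0 rose, 4 fell and 12 were not called (0 and 6 adjusted over the list alone). The median was -0.23 (adjusted p = 1.34e-04, and adjusted p = 0.603 with an estimated correlation). None of the 4 calls there was left without WT replicate 1, WT replicate 2, 4EHP-null replicate 1 or 4EHP-null replicate 2. For mitochondrial ribosomal proteins, of 77 measured, 0 rose, 13 fell and 64 were not called (0 and 13 adjusted over the list alone). The median was -0.16 (adjusted p = 1.02e-07, and adjusted p = 0.603 with an estimated correlation). MRPL12 (-0.64 ± 0.10) and MRPS16 (-0.64 ± 0.08) fell within runs of neighbours, and the 13 became 7 and 4 without WT replicate 1 and 2 and 6 and 4 without 4EHP-null replicate 1 and 2. For nuclear-encoded oxidative phosphorylation genes, of 43 measured, 1 rose, 7 fell and 35 were not called (1 and 9 adjusted over the list alone). The median was -0.16 (adjusted p = 5.16e-04, and adjusted p = 0.703 with an estimated correlation), with COX5A (-0.52 ± 0.08, in a run of neighbours) down.

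Adhesion and lineage genes went both ways in 4EHP-null mRNA. Protocadherins, cell adhesion genes with shared sequence whose read assignment is uncertain, fell: of 35 measured, 2 rose, 23 fell and 10 were not called (5 and 23 adjusted over the list alone). The median was -1.14 (adjusted p = 1.96e-10, and adjusted p = 0.603 with an estimated correlation). PCDHGC3 (-1.13 ± 0.15) and PCDHGC4 (-1.19 ± 0.19) lie in a run of neighbours. Among neuronal genes, of 19 measured, 1 rose, 6 fell and 12 were not called (3 and 8 adjusted over the list alone). The median was -0.09 (adjusted p = 0.0196, and adjusted p = 0.603 with an estimated correlation). The neurofilament genes NEFM (-2.02 ± 0.14) and NEFL (-1.11 ± 0.08) fell. Collagens and other extracellular matrix genes rose, with COL3A1 (1.35 ± 0.23), COL5A2 (1.21 ± 0.14) and LAMB2 (1.06 ± 0.11) as examples: of 36 measured, 11 rose, 1 fell and 24 were not called (14 and 3 adjusted over the list alone). The median was 0.22 (adjusted p = 4.68e-04, and adjusted p = 0.667 with an estimated correlation). The 11 became 6 without 4EHP-null replicate 2 and 7 without WT replicate 1 or WT replicate 2. Fibroblast and mesenchymal genes had 3 up and 1 down of 15 (4 and 2 adjusted over the list alone, adjusted p = 0.386), with CDH2 (0.48 ± 0.08) up and the repressor of E-cadherin SNAI2 (-1.50 ± 0.10) down. Epithelial genes had 1 up and 0 down of 9 (1 and 0 adjusted over the list alone, adjusted p = 0.530), the 1 up being the keratin KRT8 (0.99 ± 0.11). Leukocyte genes, markers of another cell type, had 0 up and 0 down of 8 (0 and 0 adjusted over the list alone, adjusted p = 0.831), and in each knockout 1 of the 8 passed an unadjusted 0.05 in edgeR and 0 were called by DESeq2 or limma-voom. Wnt targets had 3 up and 0 down of 13 (3 and 0 adjusted over the list alone, adjusted p = 0.238), with the ubiquitin ligase RNF43 (0.99 ± 0.12) up. TGF-beta and BMP targets had 0 up and 2 down of 15 (0 and 3 adjusted over the list alone, adjusted p = 0.0925). Zinc finger genes had 24 up and 14 down of 438 (23 and 11 adjusted over the list alone, adjusted p = 0.589), among them ZNF488 (1.65 ± 0.11) up and ZNF365 (-1.92 ± 0.30) down.

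Stress and interferon genes tended upward in 4EHP-null mRNA. Among integrated stress response and ATF4 target genes, of 38 measured, 10 rose, 1 fell and 27 were not called (13 and 1 adjusted over the list alone). The median was 0.19 (adjusted p = 1.34e-04, and adjusted p = 0.603 with an estimated correlation). The transcription factor ATF3 (0.80 ± 0.12) and the serine hydroxymethyltransferase SHMT2 (0.54 ± 0.09) rose. The 10 became 4 and 3 without WT replicate 1 and 2, and 7 and 3 without 4EHP-null replicate 1 and 2. Among interferon-stimulated genes, of 27 measured, 6 rose, 1 fell and 20 were not called (12 and 1 adjusted over the list alone). The median was 0.31 (adjusted p = 2.82e-04, and adjusted p = 0.603 with an estimated correlation). OAS3, which makes 2′-5′ oligoadenylates, rose (1.204 ± 0.15) and IRF7, an interferon regulatory factor, fell (-3.26 ± 0.45). The 6 that rose became 4 without WT replicate 1 or 4EHP-null replicate 2. For immediate early genes, of 28 measured, 5 rose, 0 fell and 23 were not called (5 and 0 adjusted over the list alone). The median was 0.15 (adjusted p = 0.0421, and adjusted p = 0.603 with an estimated correlation). For G1/S and DNA replication genes, of 36 measured, 3 rose, 1 fell and 32 were not called (3 and 1 adjusted over the list alone). The median was 0.07 (adjusted p = 0.0471, and adjusted p = 0.7503 with an estimated correlation), with the helicase subunit MCM2 (0.85 ± 0.10) and the polymerase subunit POLA1 (0.61 ± 0.09) up. Replication-dependent histone genes, many of which are near-identical copies with uncertain read assignment, rose: of 31 measured, 9 rose, 1 fell and 21 were not called (17 and 2 adjusted over the list alone). The median was 2.18 (adjusted p = 0.00139, and adjusted p = 0.7503 with an estimated correlation). That result followed 4EHP-null replicate 2, without which no histone gene rose and the median was -0.19. None rose without WT replicate 1 or WT replicate 2 either, and 34 rose, with more of them tested, without 4EHP-null replicate 1.

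Lists that camera did not call in 4EHP-null mRNA included the factors nearest to 4EHP itself. The 4EHP-GIGYF complex and its partners had 1 up and 1 down of 15 (1 and 1 adjusted over the list alone, adjusted p = 0.632), the loss being EIF4E2. Deadenylation, decapping and decay factors had 1 up and 3 down of 40 (1 and 3 adjusted over the list alone, adjusted p = 0.844), including the deadenylation factor NANOS1 (-1.11 ± 0.19, in a run of neighbours). The microRNA pathway had 1 up and 0 down of 13 (1 and 0 adjusted over the list alone, adjusted p = 0.638), and ribosome collision and quality control factors had 3 up and 2 down of 26 (4 and 4 adjusted over the list alone, adjusted p = 0.269), with NPLOC4 (-0.50 ± 0.08, in a run of neighbours) down. Cap binding and translation initiation factors had 3 up and 3 down of 42 (3 and 3 adjusted over the list alone, adjusted p = 0.314), with EIF5B (0.83 ± 0.13) up. ERK feedback genes had 1 up and 0 down of 16 (1 and 0 adjusted over the list alone, adjusted p = 0.760), and AU-rich element mRNAs 1 up and 0 down of 20 (1 and 0 adjusted over the list alone, adjusted p = 0.595). Unfolded protein response genes had 2 up and 1 down of 25 (4 and 1 adjusted over the list alone, adjusted p = 0.238), heat shock chaperones 1 up and 0 down of 17 (1 and 0 adjusted over the list alone, adjusted p = 0.582), and cholesterol synthesis genes 1 up and 0 down of 24 (1 and 0 adjusted over the list alone, adjusted p = 0.632). The p53 targets had 4 up and 2 down of 24 (4 and 2 adjusted over the list alone, adjusted p = 0.831), with FDXR (0.75 ± 0.13) up and AEN (-0.50 ± 0.08, in a run of neighbours) down. G2/M and mitosis genes had 2 up and 2 down of 31 (2 and 2 adjusted over the list alone, adjusted p = 0.831), and glycolysis and hypoxia genes 2 up and 2 down of 29 (2 and 2 adjusted over the list alone, adjusted p = 0.632), with the enolase ENO2 (1.03 ± 0.15) up. Over the 31 lists, 12 were called by camera at its preset correlation. The 233 called list genes (97 up, 136 down) became 109 and 96 without WT replicate 1 and 2, and 115 without 4EHP-null replicate 2.

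The comparison of GIGYF1/2-null with WT RNA-seq asks the same of the scaffold proteins that bind 4EHP. GPR50, an orphan receptor related to the melatonin receptors, rose from 5.85 ± 0.128 to 58.95 ± 3.87 CPM (3.33 ± 0.12, adjusted p = 2.82e-08). Also higher were the iodide transporter SLC5A5 (2.94 ± 0.22), ENPP2, which makes lysophosphatidic acid (2.92 ± 0.23), the p53-linked arrest gene RPRM (2.81 ± 0.20) and the synaptotagmin SYT13 (2.44 ± 0.23). TENM1 fell from 28.7 ± 2.26 to 3.08 ± 0.517 CPM (-3.22 ± 0.17, adjusted p = 7.34e-07), followed by the Rab effector SYTL5 (-2.66 ± 0.17), the secreted semaphorin SEMA3C (-1.96 ± 0.19), the transcription factor FOXP2 (-1.62 ± 0.20, in a run of neighbours) and the Pumilio-related PUM3 (-1.48 ± 0.13). In edgeR 813 genes rose and 1055 fell, 1868 in all of 15637, of which 251 and 109 changed at least 2-fold. This turned into 634 up and 540 down without genes in runs of neighbours of either knockout, and 1002 up and 868 down with upper-quartile scaling. The total was 783 without WT replicate 1, 937 without WT replicate 2 and 1082 without GIGYF1/2-null replicate 2.

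Interferon, Wnt and epithelial genes were the lists that rose in GIGYF1/2-null mRNA, with histones. Among interferon-stimulated genes, of 27 measured, 10 rose, 0 fell and 17 were not called (11 and 0 adjusted over the list alone). The median was 0.40 (adjusted p = 8.83e-05, and adjusted p = 0.497 with an estimated correlation). The double-stranded RNA sensor IFIH1 (2.44 ± 0.27) and OAS3 (2.15 ± 0.15) rose. The 10 became 5 without WT replicate 1, 4 without WT replicate 2 and 2 without GIGYF1/2-null replicate 1. For Wnt targets, of 13 measured, 4 rose, 2 fell and 7 were not called (4 and 2 adjusted over the list alone). The median was 0.27 (adjusted p = 0.0167, and adjusted p = 0.571 with an estimated correlation), with the cyclin CCND1 (1.15 ± 0.08), MYC (0.61 ± 0.10) and RNF43 (0.73 ± 0.12) up and TNFRSF19 (-1.10 ± 0.15, in a run of neighbours) down. Among epithelial genes, of 9 measured, 3 rose, 0 fell and 6 were not called (3 and 0 adjusted over the list alone). The median was 0.53 (adjusted p = 0.0167, and adjusted p = 0.571 with an estimated correlation), with the keratins KRT8 (1.26 ± 0.11) and KRT18 (0.53 ± 0.08) up. For replication-dependent histones, of 31 measured, 2 rose, 0 fell and 29 were not called (2 and 0 adjusted over the list alone). The median was 0.76 (adjusted p = 0.00494, and adjusted p = 0.718 with an estimated correlation), the pair being HIST1H1C (1.62 ± 0.28) and HIST1H2BK (0.57 ± 0.08).

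Growth, stress and ribosome lists fell in GIGYF1/2-null mRNA. Among integrated stress response and ATF4 target genes, of 38 measured, 0 rose, 9 fell and 29 were not called (0 and 10 adjusted over the list alone). The median was -0.19 (adjusted p = 1.58e-04, and adjusted p = 0.571 with an estimated correlation), with the arginine transporter SLC7A1 (-0.73 ± 0.08) and PSPH (-0.55 ± 0.10) down within runs of neighbours. The 9 became 4 and 5 without WT replicate 1 and 2, and 6 without GIGYF1/2-null replicate 2. For cholesterol synthesis, of 24 measured, 0 rose, 6 fell and 18 were not called (0 and 6 adjusted over the list alone). The median was -0.19 (adjusted p = 1.58e-04, and adjusted p = 0.577 with an estimated correlation), with the synthase HMGCS1 (-0.67 ± 0.08) down. For G1/S and DNA replication genes, of 36 measured, 0 rose, 6 fell and 30 were not called (0 and 13 adjusted over the list alone). The median was -0.19 (adjusted p = 3.93e-04, and adjusted p = 0.571 with an estimated correlation), with the polymerase subunit POLA2 (-0.47 ± 0.08) down. For G2/M and mitosis genes, of 31 measured, 0 rose, 3 fell and 28 were not called (0 and 3 adjusted over the list alone). The median was -0.16 (adjusted p = 0.0316, and adjusted p = 0.715 with an estimated correlation). For the unfolded protein response, of 25 measured, 0 rose, 4 fell and 21 were not called (0 and 5 adjusted over the list alone). The median was -0.04 (adjusted p = 0.0337, and adjusted p = 0.571 with an estimated correlation), and all 4 that fell, among them CREB3L2 (-0.96 ± 0.09) and DNAJB9 (-0.89 ± 0.12), lie in runs of neighbours. For heat shock chaperones, of 17 measured, 0 rose, 2 fell and 15 were not called (0 and 3 adjusted over the list alone). The median was -0.17 (adjusted p = 0.0316, and adjusted p = 0.715 with an estimated correlation). For cytosolic ribosomal proteins, of 78 measured, 0 rose, 4 fell and 74 were not called (0 and 4 adjusted over the list alone). The median was -0.15 (adjusted p = 1.66e-05, and adjusted p = 0.671 with an estimated correlation). RPL21 (-0.73 ± 0.10) and RPS6 (-0.67 ± 0.09) lie in runs. The median of -0.15 was -0.07 without WT replicate 2, -0.05 without GIGYF1/2-null replicate 1 and -0.25 without GIGYF1/2-null replicate 2, and 13 fell in the last case. For other 5′ TOP mRNAs, of 16 measured, 0 rose, 4 fell and 12 were not called (0 and 6 adjusted over the list alone). The median was -0.17 (adjusted p = 6.34e-05, and adjusted p = 0.571 with an estimated correlation), with TPT1 (-0.78 ± 0.09, in a run) down. The 4 became 2 without WT replicate 1 or WT replicate 2.

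Protocadherins, with uncertain read assignment, fell in GIGYF1/2-null mRNA: of 35 measured, 1 rose, 24 fell and 10 were not called (2 and 26 adjusted over the list alone). The median was -0.66 (adjusted p = 1.09e-06, and adjusted p = 0.571 with an estimated correlation). The 24 became 12 without WT replicate 1, 3 without WT replicate 2, 3 without GIGYF1/2-null replicate 1 and 3 without GIGYF1/2-null replicate 2. PCDH10, outside the clustered protocadherins, rose (0.74 ± 0.08) and PCDH7 fell (-0.57 ± 0.11). For deadenylation, decapping and decay factors, of 40 measured, 0 rose, 6 fell and 34 were not called (1 and 7 adjusted over the list alone). The median was -0.10 (adjusted p = 0.0311, and adjusted p = 0.571 with an estimated correlation), with the ubiquitin ligase CNOT4 (-0.65 ± 0.11, in a run of neighbours) down. For cap binding and initiation factors, of 42 measured, 0 rose, 3 fell and 39 were not called (0 and 2 adjusted over the list alone). The median was -0.08 (adjusted p = 0.0167, and adjusted p = 0.571 with an estimated correlation), with EIF4B (-0.58 ± 0.10) down.

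Camera called 15 of the 31 lists in GIGYF1/2-null mRNA and left the rest. Collagen and matrix genes had 9 up and 5 down of 36 (10 and 5 adjusted over the list alone, adjusted p = 0.216), with LAMB1 (-0.98 ± 0.10, in a run of neighbours) and SPARC (-0.71 ± 0.12) down. The 9 that rose became 1 without WT replicate 1, 6 without WT replicate 2 and 4 without GIGYF1/2-null replicate 2. Fibroblast and mesenchymal genes had 3 up and 4 down of 15 (3 and 4 adjusted over the list alone, adjusted p = 0.833), with SNAI2 (-1.07 ± 0.10) and ZEB2 (-0.72 ± 0.13) down. Neuronal genes had 3 up and 2 down of 19 (3 and 3 adjusted over the list alone, adjusted p = 0.850), with NEFL (0.45 ± 0.08) up and the axon guidance receptor ROBO1 (-0.40 ± 0.07) down. Zinc finger genes had 41 up and 26 down of 438 (49 and 31 adjusted over the list alone, adjusted p = 0.0957), with ZNF136 (1.55 ± 0.21) up and ZNF736 (-0.78 ± 0.10) down. Mitochondrial ribosomal proteins had 1 up and 4 down of 77 (1 and 4 adjusted over the list alone, adjusted p = 0.426), and oxidative phosphorylation genes 0 up and 1 down of 43 (0 and 0 adjusted over the list alone, adjusted p = 0.833). The 4EHP-GIGYF complex had 0 up and 2 down of 15 (0 and 3 adjusted over the list alone, adjusted p = 0.347), the microRNA pathway 2 up and 1 down of 13 (3 and 1 adjusted over the list alone, adjusted p = 0.775), and ribosome collision factors 0 up and 2 down of 26 (0 and 2 adjusted over the list alone, adjusted p = 0.386). Immediate early genes had 2 up and 0 down of 28 (1 and 0 adjusted over the list alone, adjusted p = 0.169), ERK feedback genes 1 up and 1 down of 16 (3 and 1 adjusted over the list alone, adjusted p = 0.347), and AU-rich element mRNAs 2 up and 1 down of 20 (3 and 1 adjusted over the list alone, adjusted p = 0.169). The p53 targets had 2 up and 2 down of 24 (3 and 3 adjusted over the list alone, adjusted p = 0.833), with PHLDA3 (0.84 ± 0.13) up. TGF-beta and BMP targets had 3 up and 2 down of 15 (3 and 2 adjusted over the list alone, adjusted p = 0.271). Glycolysis and hypoxia genes had 2 up and 3 down of 29 (2 and 3 adjusted over the list alone, adjusted p = 0.775), with NDRG1 (0.65 ± 0.08) up and the hexokinase HK2 (-0.74 ± 0.09) down, and leukocyte genes 0 up and 0 down of 8 (0 and 0 adjusted over the list alone, adjusted p = 0.932). The 208 called list genes (85 up, 123 down) became 99 and 91 without WT replicate 1 and 2, and 125 without GIGYF1/2-null replicate 2.

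Genes that moved the same way in both knockouts bear on whether 4EHP and GIGYF1/2 act on the same mRNAs. ANK1, a membrane skeleton ankyrin, rose in 4EHP-null (1.51 ± 0.19) and GIGYF1/2-null mRNA (1.43 ± 0.19). The p38 kinase MAPK13 rose by 1.69 ± 0.19 and 2.28 ± 0.18 in the same order, RPRM by 1.27 ± 0.22 and 2.81 ± 0.20, and GPR50 by 1.48 ± 0.12 and 3.33 ± 0.12. FAM129A (1.64 ± 0.18 and 1.35 ± 0.18) and FHAD1 (1.57 ± 0.15 and 1.56 ± 0.15) were higher in both. Lower in both were TENM1, SNAI2, DPYSL4 (-1.02 ± 0.14 and -0.80 ± 0.13), SHISA2 (-1.47 ± 0.15 and -1.43 ± 0.15) and PCDHGC3. SHISA2 and PCDHGC3 lie in runs of neighbours. In all, 219 genes rose in both, 127 fell in both and 115 moved in opposite directions. Without genes in runs of neighbours of either knockout, such as the protocadherins, the 127 became 55. Independent lists would share 52.6, 69.9 and 122. Simulated unchanged groups shared at most 2 up and 2 down, but gave at most 7 calls for 4EHP-null, too few to judge overlaps of lists this long. The 219 became 65 and 86 without WT replicate 1 and 2, and 133 and 118 without 4EHP-null replicate 1 and 2. The 127 became 36, 31, 72 and 62 in that order, and the 115 became 37, 31, 71 and 53, then 184 and 75 without GIGYF1/2-null replicate 1 and 2. Across genes, which are not independent replicates, the covariance of the fold changes was 0.0554 against 0.0302 in 50 simulations (0.0287 to 0.0321), while 56.9% of genes had the same sign against 66.6% simulated and Pearson's r was 0.201 against 0.493. Both knockouts share their WT libraries, 2 controls are too few to give each knockout its own pair, and part of the excess in overlap and covariance may come from them.

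The direct comparison of the knockouts asks where GIGYF1/2 loss and 4EHP loss differ in mRNA. SALL3 was higher in GIGYF1/2-null than in 4EHP-null cells (6.20 ± 0.37, adjusted p = 2.61e-07), as were the BMP antagonist CHRDL1 (5.57 ± 0.30) and the proteoglycan SPOCK1 (4.88 ± 0.38). Lower were BST2 (-4.17 ± 0.13, adjusted p = 1.66e-09), GFRA3 (-3.97 ± 0.23), SYTL5 (-3.69 ± 0.16) and GPC3 (-2.51 ± 0.08). Among integrated stress response genes, of 38 measured, 0 rose, 23 fell and 15 were not called (1 and 28 adjusted over the list alone). The median was -0.40 (adjusted p = 1.50e-08, and adjusted p = 0.803 with an estimated correlation). The 23 became 14 without 4EHP-null replicate 2. For G1/S genes, of 36 measured, 2 rose, 17 fell and 17 were not called (2 and 19 adjusted over the list alone). The median was -0.22 (adjusted p = 5.76e-05, and adjusted p = 0.803 with an estimated correlation). Cholesterol synthesis genes were lower (median -0.20, adjusted p = 7.48e-04, and adjusted p = 0.803 with an estimated correlation). The unfolded protein response list was lower (median -0.16, adjusted p = 0.00637, and adjusted p = 0.803 with an estimated correlation), as were heat shock chaperones (median -0.30, adjusted p = 0.0337, and adjusted p = 0.803 with an estimated correlation), whose mean was 0.02. Cytosolic ribosomal proteins were higher (median 0.21, adjusted p = 6.56e-07, and adjusted p = 0.803 with an estimated correlation), as were mitochondrial ribosomal proteins (median 0.17, adjusted p = 2.29e-06, and adjusted p = 0.803 with an estimated correlation), oxidative phosphorylation genes (median 0.17, adjusted p = 0.00292, and adjusted p = 0.803 with an estimated correlation) and protocadherins (median 0.48, adjusted p = 0.0108, and adjusted p = 0.803 with an estimated correlation). In edgeR 1788 genes were higher and 2032 lower (2298 and 1616 with upper-quartile scaling), 3820 in all, and 2426, 2238 and 2414 without 4EHP-null replicate 1, 4EHP-null replicate 2 and GIGYF1/2-null replicate 2. The 348 called list genes became 196 without 4EHP-null replicate 2.

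**Figure D2:**
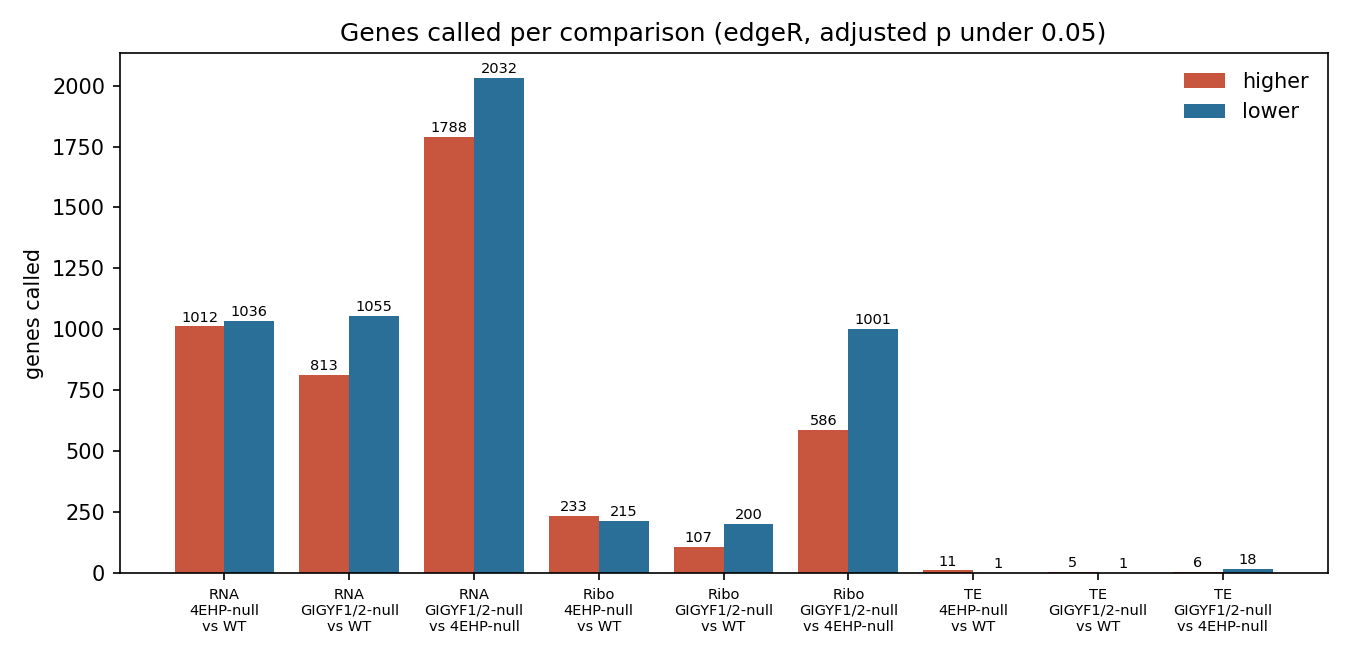
Number of genes that rose and fell (bars, adjusted p < 0.05 in edgeR) for each comparison of genotypes in RNA-seq, Ribo-seq and translation efficiency. RNA-seq bars reach 1012 up and 1036 down for 4EHP-null and 813 up and 1055 down for GIGYF1/2-null against WT, while translation efficiency reaches 11 and 1, and 5 and 1.

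Ribo-seq of 4EHP-null against WT asks which mRNAs carry more or fewer ribosomes. BST2 rose from 3.65 ± 0.859 to 73.7 ± 0.635 CPM (4.29 ± 0.18, adjusted p = 4.37e-07) and GFRA3 rose by 3.98 ± 0.36. TENM1 fell from 207 to 3 counts over 2 libraries each, 54.4-fold lower after scaling (counting interval 18.4 to 266), and SFRP1 fell from 87 to 2 counts, 34.3-fold lower (9.22 to 288). NELL2 (-4.10 ± 0.31) and ALDH1A2, which makes retinoic acid (-3.10 ± 0.27), fell, as did NEFM (-2.47 ± 0.29) and NEFL (-1.17 ± 0.16). CHRDL1 had 0 counts in both 4EHP-null libraries and was at least 3.28-fold lower than WT against a floor of 3 counts per library, a call that ended without WT replicate 2, 4EHP-null replicate 1 or 4EHP-null replicate 2. The SNAR-A genes, non-coding copies with identical counts and uncertain assignment, rose by 2.87 ± 0.53, a call that ended in DESeq2 and without WT replicate 1 or 4EHP-null replicate 2. Of 14722 genes tested with edgeR, 233 rose and 215 fell, 448 in all, and 93 of the 448 were not protein-coding. With protein-coding genes alone 170 rose and 210 fell, and with a stricter filter on low counts 231 rose and 144 fell. The total was 131 (85 up and 46 down), 132 (69 and 63), 124 (88 and 36) and 118 (85 and 33) without WT replicate 1, WT replicate 2, 4EHP-null replicate 1 and 4EHP-null replicate 2, and 712 and 751 without GIGYF1/2-null replicate 1 and 2.

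Interferon-stimulated genes also gained ribosome-protected fragments in 4EHP-null cells: of 24 measured, 4 rose, 1 fell and 19 were not called (9 and 1 adjusted over the list alone). The median was 0.50 (adjusted p = 3.45e-06, and adjusted p = 0.303 with an estimated correlation). The 4 that rose became 1 without WT replicate 1, WT replicate 2, 4EHP-null replicate 1 or 4EHP-null replicate 2. OAS3 rose by 1.23 ± 0.24 and lost its call without WT replicate 1 or 2 or 4EHP-null replicate 1 or 2. For neuronal genes, of 16 measured, 0 rose, 4 fell and 12 were not called (0 and 5 adjusted over the list alone). The median was -0.47 (adjusted p = 0.00182, and adjusted p = 0.433 with an estimated correlation). For zinc finger genes, of 476 measured, 9 rose, 1 fell and 466 were not called (8 and 1 adjusted over the list alone). The median was 0.13 (adjusted p = 0.00248, and adjusted p = 0.842 with an estimated correlation), with ZNF22 (1.19 ± 0.17) up and ZNF503 (-1.13 ± 0.15) down, both in runs of neighbours. For protocadherins, of 37 measured, 0 rose, 4 fell and 33 were not called (2 and 23 adjusted over the list alone). The median was -1.65 (adjusted p = 7.17e-06, and adjusted p = 0.791 with an estimated correlation). Mitochondrial ribosomal proteins had 0 up and 2 down (median -0.17, adjusted p = 1.09e-05, and adjusted p = 0.433 with an estimated correlation) and oxidative phosphorylation genes 0 up and 3 down (median -0.15, adjusted p = 2.92e-04, and adjusted p = 0.791 with an estimated correlation). For cytosolic ribosomal proteins no gene was called in edgeR (median -0.16, adjusted p = 4.70e-05, and adjusted p = 0.861 with an estimated correlation), where 6 passed at an unadjusted p under 0.05, 3 were called by DESeq2 and 0 by limma-voom. None was called for TGF-beta and BMP targets (median -0.23, adjusted p = 0.0294, and adjusted p = 0.509 with an estimated correlation), where 3 passed unadjusted and 0 were called by DESeq2 or limma-voom. The 44 called list genes (23 up, 21 down) became 13, 12, 14 and 15 without WT replicate 1, WT replicate 2, 4EHP-null replicate 1 and 4EHP-null replicate 2, and 70 without GIGYF1/2-null replicate 1 or GIGYF1/2-null replicate 2.

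Ribo-seq of GIGYF1/2-null against WT asks the same for the scaffolds. ENPP2 (3.28 ± 0.21, adjusted p = 2.79e-05), GPR50 (3.10 ± 0.16), IFIH1 (2.71 ± 0.23), CHRDL1 (2.62 ± 0.29), the transcriptional coregulator CITED1 (2.44 ± 0.16), OAS3 (2.35 ± 0.22) and CCND1 (1.41 ± 0.14) rose. TENM1 (-3.37 ± 0.29, adjusted p = 1.58e-04), SYTL5 (-2.58 ± 0.33), annexin ANXA1 (-1.90 ± 0.22), SEMA3C (-1.84 ± 0.28) and the G-quadruplex helicase DHX36 (-1.79 ± 0.15) fell. PARP4 (-1.91 ± 0.15), SLC7A1 (-1.05 ± 0.14) and CREB3L2 (-1.07 ± 0.14) fell within runs of neighbours. In edgeR 107 genes rose and 200 fell, 307 in all, against 64 and 60 without genes in runs of neighbours and 132 and 139 with upper-quartile scaling. The total was 62, 59, 192 and 191 without WT replicate 1, WT replicate 2, 4EHP-null replicate 1 and 4EHP-null replicate 2, and 671 and 152 without GIGYF1/2-null replicate 1 and 2. In Ribo-seq 21 genes rose and 7 fell in both knockouts, with 10 in opposite directions, against 1.69, 2.92 and 4.73 for independent lists. Simulated unchanged groups shared at most 2 up and 1 down and gave at most 5 calls for 4EHP-null, too few to judge these overlaps. The covariance was 0.0673 against 0.0370 simulated. Same signs (59.8% against 66.3%) and Pearson's r (0.311 against 0.489) again cannot be judged.

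Camera called 19 lists in GIGYF1/2-null Ribo-seq, led by interferon-stimulated genes: of 24 measured, 2 rose, 0 fell and 22 were not called (8 and 0 adjusted over the list alone). The median was 0.41 (adjusted p = 1.16e-06, and adjusted p = 0.274 with an estimated correlation). Cholesterol synthesis genes fell, with HMGCS1 (-0.81 ± 0.14, a call that ended without WT replicate 1 or WT replicate 2) as an example: of 24 measured, 0 rose, 2 fell and 22 were not called (0 and 6 adjusted over the list alone). The median was -0.17 (adjusted p = 6.91e-04, and adjusted p = 0.414 with an estimated correlation). For G2/M and mitosis genes, of 31 measured, 0 rose, 2 fell and 29 were not called (0 and 6 adjusted over the list alone). The median was -0.23 (adjusted p = 1.62e-04, and adjusted p = 0.414 with an estimated correlation). For G1/S genes, of 36 measured, 0 rose, 1 fell and 35 were not called (0 and 5 adjusted over the list alone). The median was -0.22 (adjusted p = 6.16e-04, and adjusted p = 0.414 with an estimated correlation). Among integrated stress response genes, of 38 measured, 0 rose, 2 fell and 36 were not called (0 and 2 adjusted over the list alone). The median was -0.23 (adjusted p = 6.91e-04, and adjusted p = 0.414 with an estimated correlation). Protocadherins had 1 up and 1 down (median -1.08, adjusted p = 8.53e-04, and adjusted p = 0.582 with an estimated correlation), the unfolded protein response 0 up and 2 down (median -0.12, adjusted p = 0.00597, and adjusted p = 0.414 with an estimated correlation), and zinc finger genes 3 up and 2 down (median 0.08, adjusted p = 0.0237, and adjusted p = 0.613 with an estimated correlation). ERK feedback genes had CCND1 up and no other call (median 0.39, adjusted p = 0.0175, and adjusted p = 0.414 with an estimated correlation), and epithelial genes 1 up (median 0.49, adjusted p = 0.0175, and adjusted p = 0.414 with an estimated correlation). No gene was called within cytosolic ribosomal proteins (median 0.13, adjusted p = 0.00482, and adjusted p = 0.613 with an estimated correlation), other 5′ TOP mRNAs (median -0.10, adjusted p = 0.0175, and adjusted p = 0.613 with an estimated correlation), ribosome collision factors (median -0.15, adjusted p = 0.00776, and adjusted p = 0.414 with an estimated correlation) or heat shock chaperones (median -0.27, adjusted p = 0.0144, and adjusted p = 0.613 with an estimated correlation). The same held for decay factors (median -0.11, adjusted p = 0.0123, and adjusted p = 0.414 with an estimated correlation), initiation factors (median -0.08, adjusted p = 0.0168, and adjusted p = 0.582 with an estimated correlation), immediate early genes (median 0.19, adjusted p = 0.0225, and adjusted p = 0.414 with an estimated correlation), TGF-beta and BMP targets (median 0.32, adjusted p = 0.0144, and adjusted p = 0.414 with an estimated correlation) and histones (median 0.16, adjusted p = 0.00153, and adjusted p = 0.640 with an estimated correlation). In these 9 lists edgeR had 4, 4, 7, 3, 9, 5, 5, 4 and 3 genes at an unadjusted p under 0.05, in the order named. DESeq2 called 1 each in ribosome collision factors, decay factors, immediate early genes, TGF-beta and BMP targets and histones, and limma-voom 1 each in ribosome collision factors and histones. The 31 called list genes (11 up, 20 down) became 7 without WT replicate 1 or WT replicate 2, 20 without 4EHP-null replicate 1 or 2, and 66 without GIGYF1/2-null replicate 1.

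Between the knockouts, SFRP1 had 162 Ribo-seq counts in GIGYF1/2-null and 2 in 4EHP-null cells, 58.7-fold higher (counting interval 16.0 to 489), and CHRDL1 was at least 21.5-fold higher. NELL2 (5.28 ± 0.28, adjusted p = 1.94e-06) and BEX5 (4.29 ± 0.47) were higher, and BST2 (-3.94 ± 0.17, adjusted p = 6.58e-07), SYTL5 (-3.79 ± 0.30), GFRA3 (-3.71 ± 0.33) and GPC3 (-2.62 ± 0.14) lower. Among integrated stress response genes, of 38 measured, 0 rose, 10 fell and 28 were not called (1 and 16 adjusted over the list alone). The median was -0.28 (adjusted p = 9.65e-06, and adjusted p = 0.60 with an estimated correlation). For TGF-beta and BMP targets, of 14 measured, 5 rose, 0 fell and 9 were not called (8 and 0 adjusted over the list alone). The median was 0.66 (adjusted p = 4.31e-04, and adjusted p = 0.591 with an estimated correlation). Cytosolic ribosomal proteins were higher as a list (median 0.29, adjusted p = 1.93e-08, and adjusted p = 0.60 with an estimated correlation), with 4 genes up, none of them called without 4EHP-null replicate 2. Also higher among the 13 called lists were mitochondrial ribosomal proteins (median 0.21, adjusted p = 6.25e-06, and adjusted p = 0.591 with an estimated correlation), oxidative phosphorylation genes (median 0.18, adjusted p = 0.00319, and adjusted p = 0.60 with an estimated correlation), histones (median 0.19, adjusted p = 5.33e-04, and adjusted p = 0.766 with an estimated correlation) and neuronal genes (median 0.22, adjusted p = 0.0251, and adjusted p = 0.60 with an estimated correlation). Lower were G1/S genes (median -0.22, adjusted p = 4.01e-04, and adjusted p = 0.60 with an estimated correlation), G2/M genes (median -0.16, adjusted p = 0.00319, and adjusted p = 0.60 with an estimated correlation), cholesterol synthesis (median -0.21, adjusted p = 0.00319, and adjusted p = 0.60 with an estimated correlation), heat shock chaperones (median -0.28, adjusted p = 0.0171, and adjusted p = 0.766 with an estimated correlation), ribosome collision factors (median -0.20, adjusted p = 0.0251, and adjusted p = 0.60 with an estimated correlation) and decay factors (median -0.09, adjusted p = 0.0450, and adjusted p = 0.60 with an estimated correlation). In edgeR 586 genes were higher and 1001 lower (825 and 835 with upper-quartile scaling), 1587 in all, and 431, 745 and 1043 without 4EHP-null replicate 1, 4EHP-null replicate 2 and GIGYF1/2-null replicate 2. The 169 called list genes became 55, 100 and 106 in the same order.

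**Figure D3:**
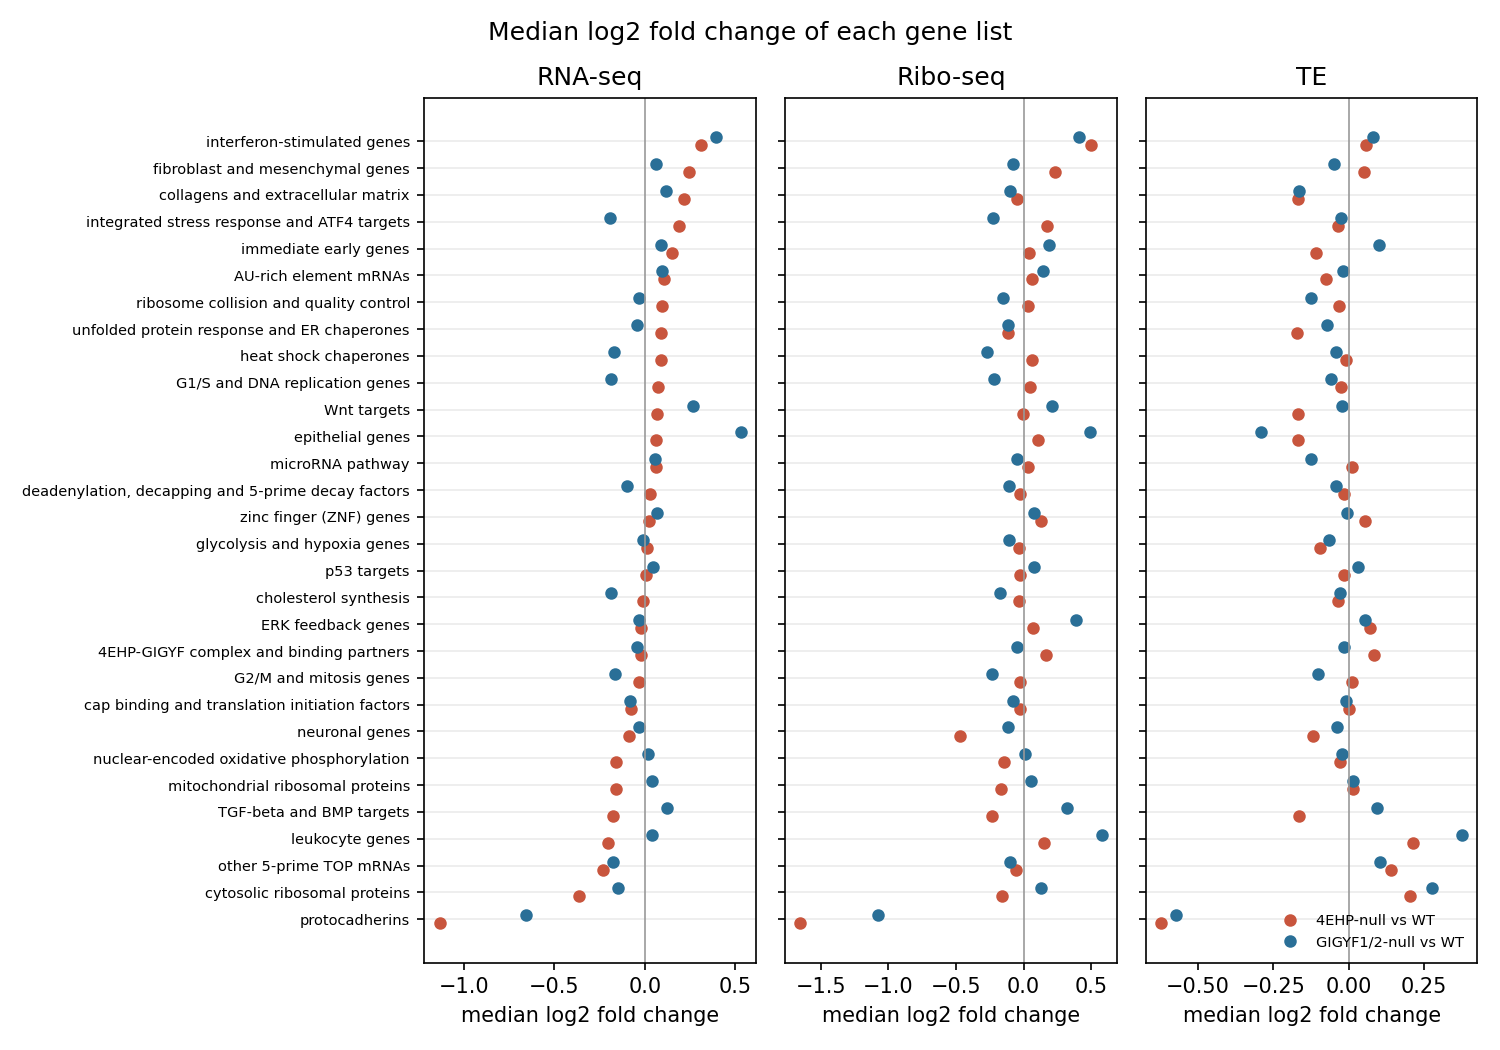
Median log2 fold change against WT of 30 gene lists (histones left out) in RNA-seq, Ribo-seq and translation efficiency for both knockouts. Cytosolic ribosomal proteins lie at -0.36 and -0.15 in 4EHP-null and GIGYF1/2-null RNA-seq, and protocadherins at -1.14 and -0.66.

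Translation efficiency (TE) is the change in ribosome-protected fragments beyond that in mRNA. NRXN3 rose in 4EHP-null TE (4.11 ± 0.34, adjusted p = 6.57e-05). Its mRNA fell from 11.0 to 0.305 and Ribo-seq from 14.6 to 7.06 CPM. C3orf62 (2.25 ± 0.21) and the telomere maintenance gene CTC1 (2.00 ± 0.20) rose. C3orf62 Ribo-seq rose from 344 ± 12.7 to 1712 ± 267 CPM. These calls held in all fits that left out a library. FSD2, NANOS1, ZNF726 and AHNAK2 were called and lost their calls in 5 to 9 of those fits, in each case without WT RNA-seq replicate 1, WT RNA-seq replicate 2 or 4EHP-null Ribo-seq replicate 1, among others. The others were the non-coding genes LINC01419, LOC100506127, SNORD17 and SNORD77, named after their values were seen. In GIGYF1/2-null TE, C3orf62, MLLT3, ORAI2 and SMARCA2 rose. Their calls were lost in 6 to 11 of those fits, in each case without WT RNA-seq replicate 1, either GIGYF1/2-null RNA-seq library or WT Ribo-seq replicate 2, among others. The non-coding LINC01000, also higher, was named after its values were seen. Between the knockouts NRXN3 (-3.78 ± 0.34), SLC5A5 (-3.90 ± 0.40) and TRIM58 (-3.94 ± 0.44) were lower in GIGYF1/2-null cells. Their 4EHP-null mRNA was at 0.305 to 0.645 CPM. EIF4E2 was not called in 4EHP-null TE (adjusted p = 0.988), nor GIGYF1 in GIGYF1/2-null TE (adjusted p = 0.665). Between the knockouts GIGYF1 was lower in TE (-1.56 ± 0.28, adjusted p = 0.0399), a call that ended in 9 of those fits.

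Of 13257 genes tested in TE, 11 rose and 1 fell in 4EHP-null cells, 5 rose and 1 fell in GIGYF1/2-null cells, and 6 were higher and 18 lower between the knockouts. With a block for replicate number these were 49 up and 38 down, 13 and 12, and 36 and 74, so the excess of rises against WT depended on the model. At an unadjusted p under 0.05 edgeR had 1022, 586 and 845 genes. The 12 in 4EHP-null cells became 5 without WT RNA-seq replicate 1, WT RNA-seq replicate 2 or 4EHP-null Ribo-seq replicate 1, and 7 without WT Ribo-seq replicate 1 or 2. They became 19 without GIGYF1/2-null Ribo-seq replicate 1 or 2, and 59 (10 up, 49 down) without 4EHP-null RNA-seq replicate 1. The 6 in GIGYF1/2-null cells became 1 to 3 without any 1 of the 4 WT libraries, without either GIGYF1/2-null RNA-seq library, without either 4EHP-null Ribo-seq library, or without GIGYF1/2-null Ribo-seq replicate 2. The 24 became 13 without WT RNA-seq replicate 1 or 2 or 4EHP-null RNA-seq replicate 2, and 11 and 9 without GIGYF1/2-null RNA-seq replicate 1 and 2. They became 7 without 4EHP-null Ribo-seq replicate 1 and 50 (41 up, 9 down) without 4EHP-null RNA-seq replicate 1. Cytosolic ribosomal proteins were higher in TE as a list in 4EHP-null cells (median 0.20, adjusted p = 7.52e-11, and adjusted p = 0.954 with an estimated correlation) and GIGYF1/2-null cells (median 0.28, adjusted p = 2.69e-23, and adjusted p = 0.488 with an estimated correlation). No gene among them was called in edgeR, where 3 and 10 passed at an unadjusted p under 0.05, or by DESeq2 or limma-voom. Other 5′ TOP mRNAs (median 0.14, adjusted p = 0.00505, and adjusted p = 0.954 with an estimated correlation) and zinc finger genes (median 0.05, adjusted p = 0.00611, and adjusted p = 0.954 with an estimated correlation) were higher in 4EHP-null TE. Unfolded protein response genes (median -0.17, adjusted p = 0.00611, and adjusted p = 0.348 with an estimated correlation), collagen and matrix genes (median -0.17, adjusted p = 0.0199, and adjusted p = 0.954 with an estimated correlation), protocadherins (median -0.62, adjusted p = 0.00611, and adjusted p = 0.954 with an estimated correlation) and histones (median -2.19, adjusted p = 8.93e-05, and adjusted p = 0.954 with an estimated correlation) were lower. The histone median turned to 0.15 without 4EHP-null RNA-seq replicate 2 and was -3.58, with 33 genes down, without 4EHP-null RNA-seq replicate 1. Lower in GIGYF1/2-null TE were ribosome collision factors (median -0.12, adjusted p = 0.0303, and adjusted p = 0.488 with an estimated correlation), collagen and matrix genes (median -0.16, adjusted p = 0.0131, and adjusted p = 0.810 with an estimated correlation), protocadherins (median -0.57, adjusted p = 0.0167, and adjusted p = 0.823 with an estimated correlation) and histones (median -0.65, adjusted p = 0.0248, and adjusted p = 0.823 with an estimated correlation). Of 279 list tests over all comparisons 88 were called by camera, none of them with an estimated correlation. The 12 called in TE became 3 without WT Ribo-seq replicate 2, 24 without GIGYF1/2-null Ribo-seq replicate 1 and 20 with a block for replicate number. In 42 of the 279 the median, the mean and the test differed in sign, and 1 of these was called, the heat shock chaperones between the knockouts.

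BST2, TENM1 and NELL2 moved alike in both assays. Across 13257 genes, which are not independent replicates, Pearson's r was 0.545 for 4EHP-null against WT, 0.615 for GIGYF1/2-null against WT and 0.697 between the knockouts, with Spearman's rho of 0.535, 0.608 and 0.699. With no filter on low counts Pearson's r was 0.194, 0.182 and 0.291, and with a stricter one 0.661, 0.735 and 0.798. Of the 1902, 1712 and 3475 genes called in RNA-seq and measured in both assays, 92.9%, 95.3% and 95.2% had the same sign in Ribo-seq. Their median ratio of Ribo-seq to RNA-seq log2 fold change was 0.812, 0.911 and 0.974. In 4EHP-null cells 126 genes rose and 158 fell in both assays, in GIGYF1/2-null cells 87 rose and 186 fell.

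**Figure D4:**
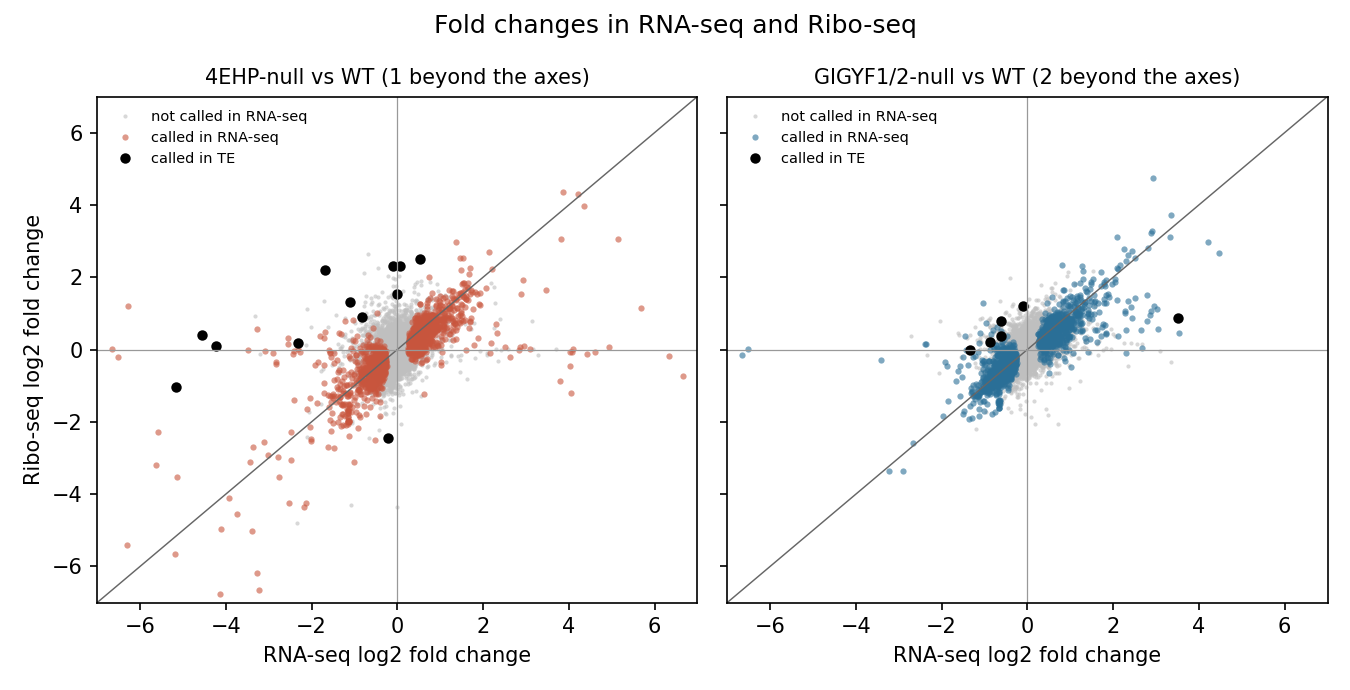
Log2 fold change in Ribo-seq (vertical axis) against RNA-seq (horizontal axis) for each knockout against WT, with a point per gene over 13257 genes. Pearson's r across genes is 0.545 for 4EHP-null and 0.615 for GIGYF1/2-null cells, and 1 and 2 genes lie beyond the axes.

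Some of the called genes were neighbours that moved together, a test added after the data were examined. In 4EHP-null mRNA, FAM21C and ARHGAP22 belong to 26 neighbours from CXCL12 to CSTF2T with a median of 1.45, of which 25 rose, and in Ribo-seq the median was 1.44. The 310 genes from IPMK to PPP2R2D had a median of -0.36 and the 178 from DPP8 to LYSMD4 a median of -0.38. In GIGYF1/2-null mRNA, GIGYF1 itself belongs to 196 neighbours from TSC22D4 to PAXIP1-AS1 with a median of -0.54. The 162 from MRPL57 to ZIC2 had a median of -0.58 and the 152 from AMD1 to RPS6KA2 a median of -0.40. The protocadherins from PCDHGA1 to PCDHGC5, which share reads, had a median of -1.14 in 4EHP-null and -0.67 in GIGYF1/2-null mRNA. Genes in runs made up 382 of 2048 calls (18.7%) in 4EHP-null and 487 of 1868 (26.1%) in GIGYF1/2-null mRNA. Runs held 22 of the 23 protocadherins that fell in 4EHP-null mRNA, 6 of the 13 mitochondrial ribosomal proteins and 3 of the 47 cytosolic ones. In GIGYF1/2-null mRNA they held 23 of 25 called protocadherins and 3 of 9 integrated stress response genes.

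**Figure D5:**
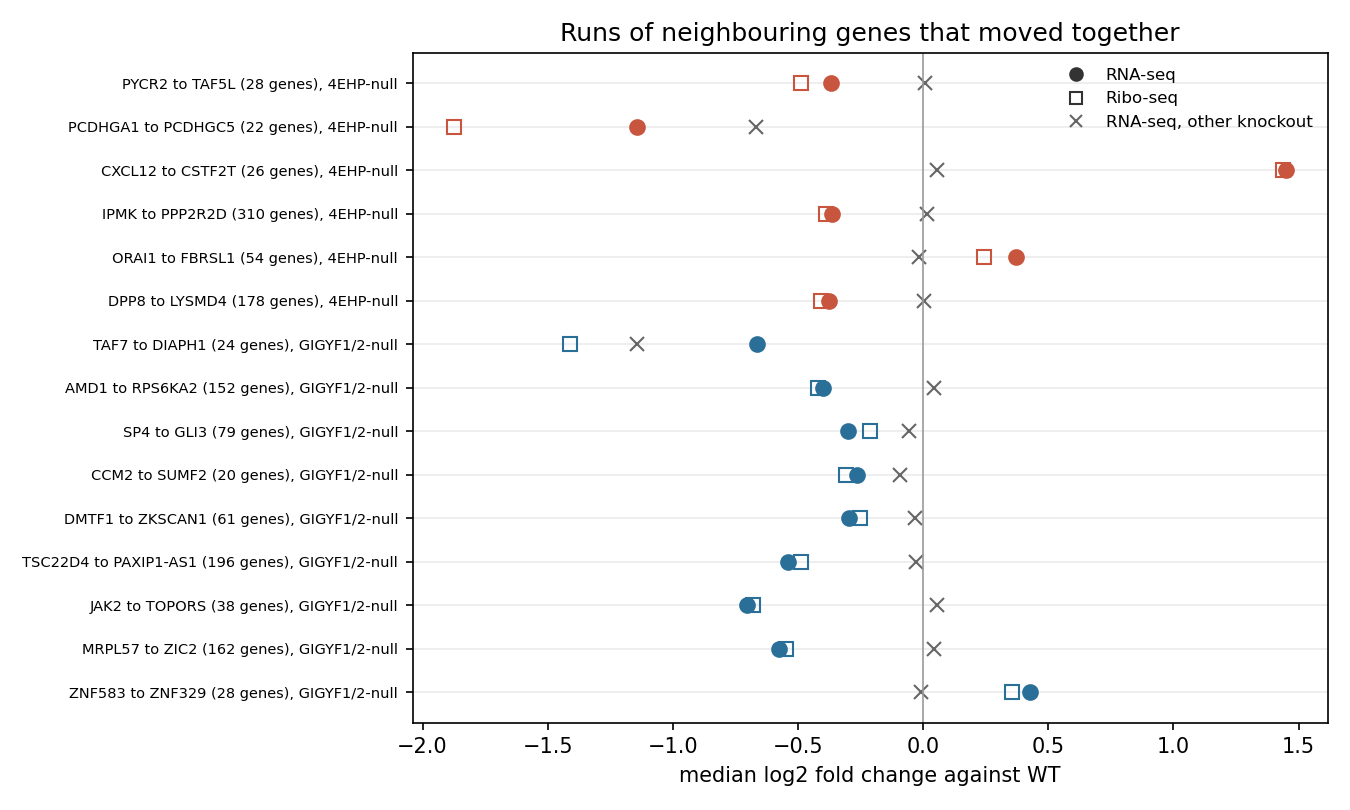
Median log2 fold change against WT of 15 runs of at least 20 neighbouring genes, in RNA-seq (filled circles), in Ribo-seq (open squares) and in RNA-seq of the other knockout (crosses). The run from CXCL12 to CSTF2T lies at 1.45 in RNA-seq and 1.44 in Ribo-seq of 4EHP-null cells and at 0.06 in GIGYF1/2-null RNA-seq.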

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

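Of the tests below, those for chance in gene order, for a function shared by 4EHP and GIGYF1/2 and for reads from other RNAs were chosen only after the result was seen. Genes are listed here because the direct comparison of the knockouts passed its threshold and the knockouts moved in opposite directions from WT. Each first value is the log2 fold change of GIGYF1/2-null over 4EHP-null cells, with the changes of 4EHP-null and GIGYF1/2-null cells against WT in parentheses. In RNA-seq CHRDL1 differed by 5.57 (-3.22 and 2.35), SPOCK1 by 4.88 (-3.39 and 1.49), NELL2 by 4.75 (-3.92 and 0.83), SLC5A5 by 4.62 (-1.68 and 2.94) and ENPP2 by 4.00 (-1.08 and 2.92). The neurofilament genes NEFM and NEFL differed by 2.45 (-2.02 and 0.44) and 1.55 (-1.11 and 0.45), and ID2 by 0.74 (-0.36 and 0.38). Lower in GIGYF1/2-null cells were SYTL5, -3.69 (1.03 and -2.66), COL3A1, -2.63 (1.35 and -1.27), GPC3, -2.51 (2.20 and -0.31), SPARC, -1.31 (0.60 and -0.71), MCM2, -1.27 (0.85 and -0.43), SESN2, -0.82 (0.41 and -0.42) and PRRC2C, -0.76 (0.37 and -0.39).

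In Ribo-seq NELL2 differed by 5.28 (-4.10 and 1.18), SYTL5 by -3.79 (1.21 and -2.58) and PARP4 by -2.52 (0.61 and -1.91). CHRDL1 had 0 Ribo-seq counts in 4EHP-null cells, so its fitted value of 9.28 depends on the prior count and the bound is at least 21.5-fold. Among lists, medians of integrated stress response genes in RNA-seq differed by -0.40 (0.19 and -0.19) and of G1/S genes by -0.22 (0.07 and -0.19), both with adjusted p = 0.803 with an estimated correlation. In Ribo-seq TGF-beta and BMP targets differed by 0.66 (-0.23 and 0.32) and cytosolic ribosomal proteins by 0.29 (-0.16 and 0.13), with adjusted p = 0.591 and 0.60 with an estimated correlation. No cause was tested for any of these gene by gene.

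Neighbouring genes moved together in RNA-seq, such as the 26 from CXCL12 to CSTF2T in 4EHP-null cells and the 162 from MRPL57 to ZIC2 in GIGYF1/2-null cells. Chance in gene order was excluded only for each knockout's most extreme running median, at least 3.27 times the highest of 200 shuffled orders. Of the 15 runs of at least 20 genes, 10 moved in the other knockout by medians of -0.112 to 0.0498 of the run's change. They were chosen for intervals under 0.25 (within -0.293 and 0.208), so a shared function is not excluded. In GIGYF1/2-null cells the runs DMTF1 to ZKSCAN1, SP4 to GLI3 and CCM2 to SUMF2 had ratios of 0.103, 0.183 and 0.351. There a shared function cannot be told apart from an effect of 1 knockout, since the intervals reached 0.262, 0.368 and 0.781. The protocadherin runs PCDHGA1 to PCDHGC5 and TAF7 to DIAPH1 fell in both knockouts, with ratios of 0.583 and 1.72, though their genes share reads and are not independent. A shared function is a candidate explanation for these, and a difference that lies in the WT cells used for both comparisons stays open and untested. Genes within a run spread around its median by 1.04 times the spread of matched genes outside runs (0.931 to 1.14), as a change of DNA copy number between the lines would give. A copy-number difference between lines is therefore a candidate explanation, and an effect of each knockout on a whole region stays open and untested.

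Cytosolic ribosomal protein mRNAs such as RPL36A were lower in 4EHP-null RNA-seq, with a list median of -0.36. Gene width and expression level do not explain all of it, since 10000 matched random lists had a median of -0.15 (-0.18 to -0.11). A single library does not explain it either, since without each library in turn the median lay between -0.41 and -0.29. The other 5′ TOP mRNAs were lower too, with a median of -0.23 at percentile 0.05 of matched lists, so a change shared by 5′ TOP mRNAs is a candidate explanation. That change may be biological, or a difference in growth between the cultures, which was not tested.

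Genes called in TE, such as C3orf62 and CTC1, had a WT ratio of Ribo-seq to RNA-seq at a median percentile of 93.2 (89.1 to 95.8), and 20 of 33 lay at or above percentile 90. Protected reads that come from other RNAs than the gene's mRNA are therefore a candidate explanation. Few protected reads as the cause cannot be told apart from a real change, since the genes' Ribo-seq level lay at a median percentile of 36.9 (28.3 to 63.2). Altered translation of these mRNAs stays open and was not tested.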

How the results depend on the processing

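Of the tests below, the fits without genes in runs and with protein-coding genes alone were chosen only after the result was seen. Among counts, correlations and list totals, 193 values stayed within the spread or within 1.5 times the reported count and 131 moved, over 16 results. Of the values for named genes and lists, 8859 stayed on the same side of the threshold, 132 passed it newly and 720 missed it. None was called in both fits with opposite signs. Changes of sign where a value was not called in both fits were not counted. Leaving out a library kept 141 to 191 of 199 named RNA-seq calls such as BST2 and TENM1, 41 to 62 of 66 in Ribo-seq and 11 to 19 of 22 in TE. DESeq2 kept 192, 60 and 21 of them, and limma-voom 195, 66 and 19. In these fits a genotype with a lone sample was assumed to vary like the others.

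Leaving out each library gave 810 to 2537 genes for 4EHP-null, 783 to 1819 for GIGYF1/2-null and 2238 to 3756 between the knockouts in RNA-seq. In Ribo-seq it gave 118 to 751, 59 to 671 and 431 to 1659, and in TE 5 to 59, 1 to 8 and 7 to 50. The genes up in both knockouts ranged from 65 to 178, down in both from 31 to 120, and opposite from 31 to 184. The correlation of RNA-seq with Ribo-seq ranged from 0.455 to 0.539 for 4EHP-null, 0.486 to 0.585 for GIGYF1/2-null and 0.605 to 0.667 between the knockouts. The called list tests ranged from 69 to 101.

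A block for replicate number gave 3571 and 3224 genes for the knockouts against WT in RNA-seq, 1830, 1747 and 3291 in Ribo-seq (4EHP-null, GIGYF1/2-null, between them), 87, 25 and 110 in TE, and overlaps of 456 up, 318 down and 353 opposite. With a term shared by RNA-seq and Ribo-seq libraries of the same genotype and replicate number, TE gave 27, 12 and 50. The numbers link libraries by number alone. Residuals of like-numbered libraries correlated across genes by 0.0701, 0.180 and 0.153 in RNA-seq, 0.149 to 0.314 in Ribo-seq and 0.0301 to 0.191 between the assays. The cause was not tested. A minimum fold of 1.2 gave 691, 764 and 1727 in RNA-seq, 246, 132 and 827 in Ribo-seq, and 1 for GIGYF1/2-null TE and 12 between the knockouts, since it asks for more than any change. With no filter on low counts, Ribo-seq gave 1166, 1135 and 2405, GIGYF1/2-null TE 10, the overlaps 342, 224 and 245, and the correlations 0.194, 0.182 and 0.291. A stricter filter gave 11 in TE between the knockouts and correlations of 0.661, 0.735 and 0.798, and the cause of either was not tested.

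With only the libraries of the genotypes compared, Ribo-seq gave 769 for 4EHP-null and 174 for GIGYF1/2-null, and TE 23 for 4EHP-null and 14 between the knockouts. DESeq2 gave 24, 10 and 37 in TE, and the newer edgeR option 3 for GIGYF1/2-null TE. The cause was not tested. Without genes in runs, GIGYF1/2-null RNA-seq gave 1174 and 4EHP-null 1417. Ribo-seq gave 289, 124 and 1032, GIGYF1/2-null TE 2 and the overlap down in both 55, with fewer genes tested. With protein-coding genes alone the 4EHP-null correlation was 0.622. Of 279 list tests, camera at its preset correlation called 88, camera with an estimated correlation called 0, and fry called 22. Upper-quartile scaling changed the balance of rises and falls where given above, and DESeq2 gave 75 up and 232 down for GIGYF1/2-null Ribo-seq. Upper-quartile scaling also called 30 cytosolic ribosomal proteins up between the knockouts in RNA-seq against 19. Of simulated 1.5-fold changes 17.9% to 23.9% were recovered in Ribo-seq and 71.6% to 82.1% in RNA-seq, assays that differ in both depth and spread, and these were not tested apart.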

Other observations

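The tests of gene families below were chosen only after the result was seen, over 182 families in RNA-seq and 181 in Ribo-seq, and none passed with an estimated correlation. Small nucleolar RNA host genes (SNHG) fell in 4EHP-null RNA-seq, 10 of 18 with a median of -0.46 (adjusted p = 1.08e-07, adjusted p = 0.833 with an estimated correlation), including SNHG5, SNHG8, SNHG6 and SNHG12. Synaptotagmin (SYT) genes, which act in vesicle fusion, rose in GIGYF1/2-null RNA-seq, 6 of 13 with a median of 0.39 (adjusted p = 0.00274, adjusted p = 0.930 with an estimated correlation), including SYT9 and SYT13. Small Cajal body RNAs (SCARNA) rose in 4EHP-null Ribo-seq, 4 of 11 with a median of 0.84 (adjusted p = 4.84e-05, adjusted p = 0.982 with an estimated correlation). DEAH-box helicases (DHX) were lower in GIGYF1/2-null Ribo-seq, with DHX36 and DHX15 called among 15 and a median of -0.47 (adjusted p = 1.52e-05, adjusted p = 0.929 with an estimated correlation).

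The non-coding RNAs RMRP, RPPH1 and MIR6087, picked after their values were seen, were not tested as a group. RMRP was at 186 CPM in 4EHP-null RNA-seq replicate 2 against 0.428 CPM in replicate 1, 0.508 and 1.24 CPM in WT and 4.49 and 14.0 CPM in GIGYF1/2-null replicates 1 and 2. RPPH1 was at 204 CPM against 0.825 CPM in 4EHP-null replicate 1, 0.746 and 1.67 CPM in WT and 5.82 and 15.3 CPM in GIGYF1/2-null cells. MIR6087 was at 204 CPM against 2.29 CPM, 1.36 and 2.55 CPM, and 5.51 and 8.83 CPM in the same order. The 4EHP-null replicate 2 library held 221 CPM of summed histone mRNA against 98.6 CPM in 4EHP-null replicate 1, 124 CPM in each WT library and 186 and 199 CPM in GIGYF1/2-null replicates 1 and 2. In Ribo-seq HSPA1A, which shares reads with HSPA1B, was at 2335 and 988 CPM in WT replicates 1 and 2, 1919 and 1152 CPM in 4EHP-null and 2618 and 729 CPM in GIGYF1/2-null replicates. Among leukocyte genes the levels in RNA-seq were low, with CD68 at 2.45, 2.32 and 2.74 CPM in WT, 4EHP-null and GIGYF1/2-null cells.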
